A study of Mus musculus with 3 samples.

How the data were processed

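Gene expression was measured on 3 Affymetrix arrays hybridised with RNA from GFP-positive cells of C57BL/6 mouse bone marrow. In these mice GFP is expressed under the control of the nestin gene promoter. Per the labels' protocols, the cells were freshly isolated and sorted by flow cytometry, and their RNA was amplified with a whole-transcript kit for very small inputs, converted to sense strands, fragmented and labelled with biotin. The 3 arrays form 1 group, with no control or comparison group among the samples used here. Array numbers 1 to 3 are those of the sample titles. The labels do not say whether the 3 samples came from separate mice or separate sorts, so the p-values measure only the spread between these samples, which may be technical.

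The deposited values were log2 expression values per probeset, made by the authors with Affymetrix Expression Console 1.1 and RMA (robust multi-array average, which corrects the background, normalises the arrays to a common distribution and summarises probes), per the submitters' processing notes. The RMA settings and the annotation build are not given in the sources used here. Each array had 1256831 probesets, with a range from 0 to 13.7 and medians of 5.20, 5.22 and 5.24 on the log2 scale. Each array held 20744 probesets at exactly 0, and values there have no order. The number of arrays limits the precision, and no read depth applies. No scanner intensities, probe sequences or scan dates were used here, so background correction, GC content of the probes and scan batches were not examined.

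Probesets were named with a table of the platform's annotation. It gave 1 gene symbol for 318760 probesets and several for 6684. The remaining 931387 probesets are unnamed here. Older symbols were updated through the synonyms of a RefSeq gene table of assembly GRCm38.p6, which changed 4227 symbols. After updating, 22040 of 22103 genes had a symbol in that table. No coordinates are given, because the build behind the array annotation is not stated. A gene's value on an array was the median of its probesets with exactly 1 symbol, and genes needed at least 4 probesets, which left 18865 genes with a median of 13 probesets each.

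With no second group, each gene was compared with a background measured on the same array. The background was the 355 olfactory, vomeronasal and bitter taste receptor genes with at least 4 probesets, which had a median of 5 probesets each. The threshold of an array was the 95th percentile of these genes. An intercept-only model was fitted with limma 3.58.1 in R 4.3.3 to each gene's value minus the threshold of the same array. The test was one-sided and its p-values were adjusted by the Benjamini-Hochberg method over all 18865 genes, with an adjusted p below 0.05 called above background. Levels of different genes are not ranked against each other, since probes differ in affinity. On simulated data with 18865 genes and the spread of the real arrays, the test called 35 of 50 genes placed 0.5 above the threshold on the log2 scale, 46 of 50 placed 1 above and 50 of 50 placed 2 above. It called 1 of 50 genes placed at the threshold and 0.265% of all 6791 genes placed at or below it. The simulation took the threshold as fixed.

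Before the data were examined, 28 lists of cell type markers and other gene groups were fixed, together with the test and the rule for named genes. For each list the members above background were counted, with p-values adjusted over all genes and, as a second count, adjusted over the list alone. The list's median on each array was placed among 10000 random lists of the same size, drawn from genes in the same of 10 bins of probeset number. For levels between arrays, each gene's deviation from its mean over the 3 arrays was taken, the array's median deviation over all genes (0.03, 0.01 and -0.04) was removed, and the list median was computed per array. The range of these 3 medians was placed among 10000 random lists matched on mean expression in 20 bins. For a simulation with 18865 genes, each gene's values were shuffled between the arrays independently of other genes, and lists were drawn at random. There 3 of 100 unchanged lists of 14 genes exceeded the 95th percentile. So did 41 of 100 with a planted shift of 0.25 in 1 array, 97 of 100 with a shift of 0.5 and 100 of 100 with a shift of 1. Shuffling removes variation shared between genes, so 3 of 100 is no error rate for the fixed lists. Percentiles describe these arrays and are not p-values.

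Named genes were all members of the niche factor and perivascular stromal lists, and up to 3 called members with the largest margin and the 1 member with the smallest margin of every other list. They also included the 10 genes outside the lists with the highest mean, leaving out ribosomal protein and mitochondrial symbols, and the 10 called genes with the largest range over the arrays. Mitochondrial genes that the RefSeq table lists without the mt- prefix were not caught by that exclusion. Other members of the lists are named where they illustrate a count, and were chosen after their values were seen. Some members of the lists were not analysed here, and 12 others had fewer than 4 probesets.

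The alternatives fixed in advance were the mean or the 75th percentile over probesets, the 99th percentile as threshold, a background from unnamed probesets, quantile normalisation of the deposited values between arrays, removal of dim probesets, a minimum of 1 or 8 probesets, a count of genes above the threshold on each array with no test, and leaving out each array in turn. A further, stricter background was added after seeing the data. It took the 95th percentile of 32 genes of the hepatocyte, photoreceptor and spermatid lists, and is called the other-tissue background. Its thresholds were 6.85, 7.02 and 6.68 on arrays 1, 2 and 3, compared with 5.40, 5.66 and 5.64 for the chemosensory genes. On each array the threshold lay between the value of Prm1 and that of Prm2 or Apoa2. These are the 3 genes of the 32 that were called above the chemosensory background, so the stricter threshold rests on them. Counts above the other-tissue background are given beside the main counts, with the same limma test and adjustment. Figures were drawn with matplotlib 3.10.9.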

Results

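The data set profiled the transcriptome of bone marrow cells that carry GFP under the nestin promoter, a reporter used to mark a rare stromal population around marrow vessels. There were 3 arrays of 1 group of sorted GFP-positive cells and no second group. The values therefore describe which genes gave a signal above background in these cells and how far the 3 arrays agreed. Across all 1256831 probesets Pearson's r was 0.901 between arrays 1 and 2, 0.919 between arrays 1 and 3, and 0.915 between arrays 2 and 3. Across 18865 genes the coefficients were 0.933, 0.947 and 0.939. These coefficients are across probesets or genes, which are not independent replicates. The median SD of a gene over the 3 arrays was 0.27 on the log2 scale.

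Of 18865 genes, 9548 (50.6%) lay above the chemosensory background in limma's one-sided test with Benjamini-Hochberg adjustment, and 3565 (18.9%) also lay above the stricter other-tissue background. The background genes themselves were called in 9 of 355 cases. Genes of hepatocytes, photoreceptors and spermatids, which serve as a check because marrow cells should lack most of them, were called in 3 of 32 cases. These were Apoa2, a liver apolipoprotein, with 7.25 ± 0.16 (SD, n = 3) on the log2 scale, and the sperm protamines Prm1 with 6.57 ± 0.19 and Prm2 with 7.21 ± 0.17. The photoreceptor list had 0 of 11 members above background by limma, also 0 at an unadjusted p below 0.05 and 0 above the threshold on all 3 arrays. Members of these lists that did not pass included the photoreceptor gene Rp1, with 3.79 ± 0.26, the hepatocyte gene Fgg, with 3.34 ± 0.04, and the spermatid gene Zpbp, with 3.75 ± 0.53.

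**Figure D1:**
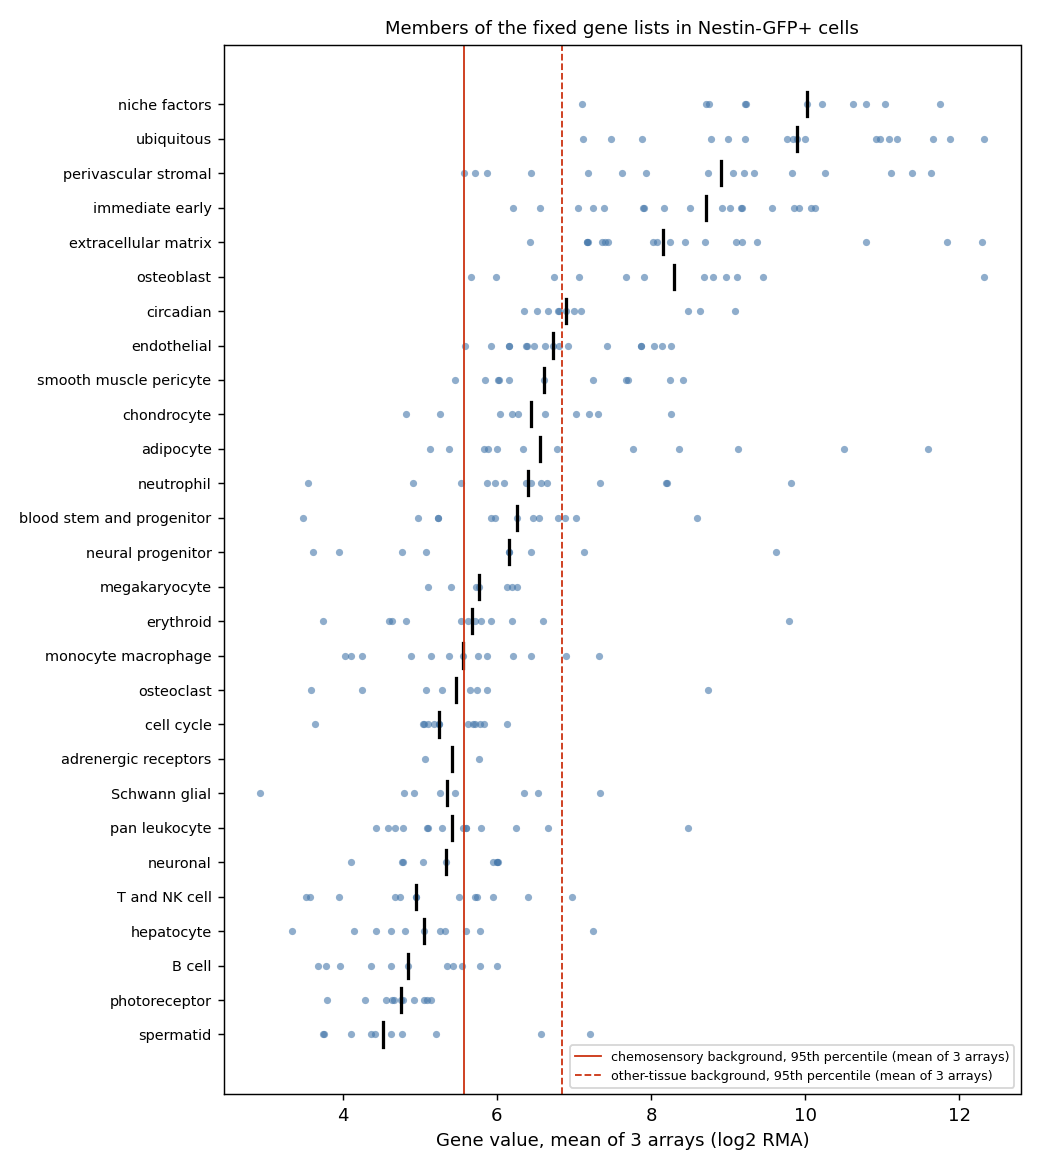
Log2 gene values (mean of 3 arrays, one point per gene) of the 28 gene lists, with the list median as a black bar. Red lines mark the chemosensory background (solid) and the other-tissue background (dashed), as the mean of the 3 arrays' thresholds. The medians of the niche factor and ubiquitous lists lie far to the right of both lines, and the B cell, photoreceptor and spermatid lists to the left of the solid line for most members.

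Genes of the niche factor list gave a strong signal in the sorted cells. All 11 measured members of the niche factor list lay above background, 11 adjusted over the list alone, and 10 lay above the other-tissue background. Cxcl12, the chemokine that retains stem cells in the marrow, stood at 11.75 ± 0.14 (SD, n = 3), and Kitl, the ligand of the Kit receptor, at 10.62 ± 0.27. Angpt1, which encodes the Tie2 ligand angiopoietin-1, stood at 11.04 ± 0.09, and the adhesion molecule Vcam1 at 10.80 ± 0.08. The lymphoid cytokine Il7 had 8.72 ± 0.32, osteopontin (Spp1) 10.22 ± 0.40, Csf1 9.22 ± 0.09, Igf1 10.03 ± 0.25 and N-cadherin (Cdh2) 8.75 ± 0.20. Bmp4 varied more, with 10.31 on array 1, 8.76 on array 2 and 8.63 on array 3. The Notch ligand Jag1, at 7.10 ± 0.16, was above the chemosensory background only. The adjusted p of limma was 2.66e-07 for Cxcl12 and 7.77e-05 for Jag1, the extremes of the list. The list's median lay above all 10000 random lists on each array, and its margin over the background median was 6.59 ± 0.28 (SD, n = 3).

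Markers of perivascular mesenchymal stroma were also above background, while nestin itself was not called. Of 16 measured members 13 lay above background, 13 adjusted over the list alone, and 11 lay above the other-tissue background. The leptin receptor gene Lepr stood at 11.38 ± 0.12 (SD, n = 3), Cdh11 at 11.63 ± 0.17, Gas6 at 11.12 ± 0.05 and the transcription factor gene Ebf3 at 10.26 ± 0.20. The platelet-derived growth factor receptor genes Pdgfra and Pdgfrb stood at 9.34 ± 0.38 and 9.83 ± 0.34. Further values were 9.20 ± 0.26 for Cd200, 9.06 ± 0.22 for Itgav, 8.74 ± 0.35 for Prrx1, 7.93 ± 0.32 for Foxc1 and 7.63 ± 0.40 for Eng. Mcam (7.18 ± 0.43) passed the chemosensory background only, and so did Nt5e, with 5.84, 7.48 and 6.01 on arrays 1, 2 and 3, whose call was lost without array 2 (adjusted p = 0.176, limma). Nes, whose promoter drives the reporter, had 5.97, 5.21 and 5.56 on arrays 1, 2 and 3, a mean of 0.01 above the threshold (adjusted p = 0.757, limma). This missing call does not show that the transcript was absent. Cspg4, the gene of the NG2 proteoglycan, had 5.87 ± 0.31 (adjusted p = 0.178, limma) and Thy1 5.72 ± 0.16 (adjusted p = 0.373, limma). With the mean over probesets in place of the median, Cspg4 passed (adjusted p = 0.00947, limma) and Nes did not (adjusted p = 0.278, limma).

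**Figure D2:**
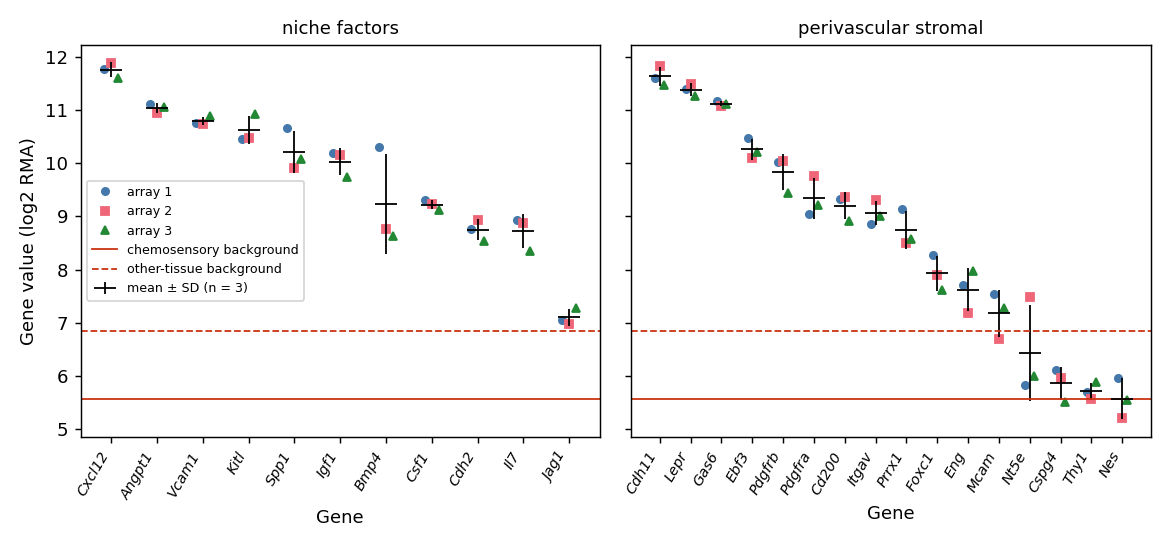
Log2 values of each measured niche factor (left) and perivascular stromal gene (right) on the 3 arrays, with mean ± SD (n = 3). Red lines are the chemosensory (solid) and other-tissue (dashed) backgrounds as means of the arrays' thresholds. Cxcl12, at 11.75, and Lepr, at 11.38, lie far above both lines, and Nes, Thy1 and Cspg4 lie near the solid line.

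Among osteoblast genes 10 of 12 lay above background, 11 adjusted over the list alone, and 8 above the other-tissue background. They included the bone sialoprotein gene Ibsp (12.33 ± 0.01, SD, n = 3), Phex (9.46 ± 0.46), the collagen gene Col1a2 (9.12 ± 0.39) and the transcription factor genes Runx2 (8.80 ± 0.05) and Sp7 (7.68 ± 0.31). The sclerostin gene Sost (5.99 ± 0.22) and Bmp2 (5.67 ± 0.06) did not pass. Among adipocyte genes 7 of 12 lay above background, 7 adjusted over the list alone, and 4 above the other-tissue background. Those 4 were the adiponectin gene Adipoq (11.60 ± 0.12), the lipase gene Lpl (10.51 ± 0.28) and the adipogenic regulators Pparg (9.13 ± 0.46) and Cebpa (7.77 ± 0.54). Fabp4 (9.05, 6.17 and 9.86 on arrays 1, 2 and 3), Cfd (6.78 ± 0.22) and the perilipin gene Plin1 (6.33 ± 0.19) passed the chemosensory background only. The 5 members that did not pass included the leptin gene Lep (5.14 ± 0.16). Among cartilage genes 7 of 10 lay above background, 7 adjusted over the list alone. Only Cnmd (8.25 ± 0.47) also lay above the other-tissue background, while Col2a1 had 7.31 ± 0.09, Chad 7.19 ± 0.57 and Matn1 4.82 ± 0.26. On arrays 1, 2 and 3 the median of the osteoblast list was above 99.99%, 99.88% and 100% of random lists, that of the adipocyte list above 91.0%, 83.9% and 93.2%, and that of the cartilage list above 86.2%, 66.4% and 85.1%.

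Extracellular matrix genes gave a broad signal, with 17 of 18 above background, 17 adjusted over the list alone, and 12 above the other-tissue background. Sparc stood at 12.30 ± 0.10 (SD, n = 3), biglycan (Bgn) at 11.85 ± 0.09 and fibrillin-1 (Fbn1) at 10.79 ± 0.04. Basement membrane and type VI collagen genes were among the called members, such as Lama4 with 9.10 ± 0.03 and Col6a1 with 9.38 ± 0.29. Postn, the gene of periostin, had 7.96, 4.72 and 6.61 on arrays 1, 2 and 3 and did not pass (adjusted p = 0.133, limma). Without array 2 Postn was called (adjusted p = 1.88e-08, limma) and the list gave 18 of 18. In that fit limma used a common variance for all genes.

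Endothelial genes had higher values on arrays 1 and 3 than on array 2, where their median was close to background. Of 17 measured members 12 lay above background, 16 adjusted over the list alone. The other-tissue background called 0 by limma, with 4 at an unadjusted p below 0.05 and 0 above that threshold on all 3 arrays. VE-cadherin (Cdh5) had 9.14 on array 1, 6.05 on array 2 and 9.58 on array 3, endomucin (Emcn) had 8.50, 6.75 and 9.16, and Pecam1 had 8.92, 6.73 and 8.46. Sox17 did not pass, with a mean of 5.59. The count was 7 without array 1, which also ended the calls of Cdh5 and Stab2, and 10 without array 3. It was 15 without array 2, where limma used a common variance for all genes. Limma's prior degrees of freedom, which set how far variances are pooled over genes, were 3.32 without array 1 and 11.8 without array 3. The lower count therefore does not by itself trace to the values of array 1. The list's median lay above 93.2% of random lists on array 1, 22.9% on array 2 and 96.1% on array 3.

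Of 11 smooth muscle and pericyte genes 8 lay above background, 9 adjusted over the list alone, and 3 above the other-tissue background. These 3 were the myosin kinase gene Mylk (8.42 ± 0.05, SD, n = 3), the potassium channel subunit gene Abcc9 (8.36, 7.10 and 9.30 on arrays 1, 2 and 3) and Notch3 (7.70 ± 0.29). The count was 5 without array 1. On arrays 1, 2 and 3 the list's median lay above 95.55%, 61.02% and 67.35% of random lists. The contractile genes Acta2 (6.03 ± 0.31) and Lmod1 (5.45 ± 0.18) were near the threshold. Schwann cell and glial genes were above background in 3 of 8 cases, 3 adjusted over the list alone, namely S100b (7.34 ± 0.87), Sox10 (6.54 ± 0.13) and Ngfr (6.35 ± 0.01). Cdh19 had 2.93 ± 0.32. Neuronal genes were called in 2 of 9 cases and in 0 adjusted over the list alone, with 4 at an unadjusted p below 0.05 and 4 above the threshold on all 3 arrays. The called genes were Tubb3 (6.02 ± 0.23) and Nefm (6.01 ± 0.22), and both calls were lost without any 1 of the arrays. The synaptic gene Snap25 had 4.11 ± 0.13. Of 9 neural progenitor genes 5 were called, 5 adjusted over the list alone, where 50.6% of all genes were called. The median of that list lay above 65.11%, 62.33% and 60.6% of random lists on arrays 1, 2 and 3. Vim, which mesenchymal cells also express, stood at 9.62 ± 0.15, Olig2 at 7.13 ± 0.21 and Neurog2 at 6.44 ± 0.32, and Fabp7 at 3.62 ± 0.34. None of these 3 neural lists had more than 1 member above the other-tissue background. The 2 adrenergic receptors measured here gave 0 calls by limma, 0 at an unadjusted p below 0.05 and 0 above the threshold on all 3 arrays, and Adra2c stood at 5.06 ± 0.21.

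Blood cell markers differed between the lists. Over the 8 blood lists 30 of 97 genes were called, and 5 lay above the other-tissue background, namely Lcp2, Ly6a, Hbb-b1, S100a8 and Camp. A called member does not by itself assign its signal to the cell type of its list. Ly6a, Hbb-b1 and Camp were lowest on array 2, as most endothelial genes were, while Lcp2 and S100a8 were not. Among all genes 50.6% were called, and 18.9% lay above the other-tissue background. The pan-leukocyte list had 3 of 14 members above background, 2 adjusted over the list alone, namely Lcp2 (8.48 ± 0.51, SD, n = 3), Rac2 (6.67 ± 0.46) and Hcls1 (6.24 ± 0.71). Ptprc, the gene of CD45, had 4.68 ± 0.40 and Vav1 4.43 ± 0.18, and the list's median was above 1.75%, 0.75% and 9.07% of random lists on arrays 1, 2 and 3. B cell genes gave 0 of 11 calls by limma, 1 at an unadjusted p below 0.05 and 1 above the threshold on all 3 arrays, and Rag2 stood at 3.68 ± 0.22. T and NK cell genes gave 2 of 13, also 2 adjusted over the list alone, with Tcf7 at 6.98 ± 0.26, Prf1 at 6.40 ± 0.27 and Klrb1c at 3.52 ± 0.47. The megakaryocyte list gave 2 of 7, also 2 adjusted over the list alone, with Gp9 at 6.26 ± 0.17, Treml1 at 6.13 ± 0.13 and Gp6 at 5.11 ± 0.16. The call of Treml1, like that of Hcls1, was lost without array 1 and without array 3.

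Neutrophil genes gave 9 of 14 calls, 9 adjusted over the list alone. The median of that list lay above 82.28%, 85.16% and 87.02% of random lists on arrays 1, 2 and 3. S100a8, an abundant neutrophil transcript, stood at 9.81 ± 0.44 (SD, n = 3), the cathelicidin gene Camp at 8.20 ± 0.33, and the myeloperoxidase gene Mpo at 6.59, 8.28 and 9.69 on arrays 1, 2 and 3, while Mmp8 had 3.55 ± 0.39. Monocyte and macrophage genes gave 4 of 13 calls, 3 adjusted over the list alone. Mrc1 had 8.39 on array 1, 4.44 on array 2 and 9.15 on array 3, Lyz2 had 5.93, 6.72 and 8.03, C1qb stood at 6.44 ± 0.37 and Ms4a7 at 4.03 ± 0.36. The count was 2 without array 1, and the call of Mrc1 was lost without array 1 and without array 3. Erythroid genes gave 3 of 12 calls, 3 adjusted over the list alone, with the globin gene Hbb-b1 at 10.49, 8.33 and 10.56, Car2 at 6.60 ± 0.59, Epor, whose call was lost without array 1, at 6.19 ± 0.31 and Rhag at 3.75 ± 0.30. Hbb-b1 shares sequence with other beta-globin genes, so its signal may include theirs. Stem and progenitor markers gave 7 of 13 calls, 7 adjusted over the list alone, with Ly6a at 8.90, 7.58 and 9.30 on arrays 1, 2 and 3, Tal1 at 7.02 ± 0.11, Meis1 at 6.88 ± 0.39 and Slamf1 at 3.49 ± 0.14. This count is near the 50.6% called among all genes. The list's median lay above 41.98%, 25.83% and 78.95% of random lists on arrays 1, 2 and 3. In the osteoclast list 1 of 8 was called, also 1 adjusted over the list alone. That gene was the protease gene Ctsk (8.74 ± 0.27), and Atp6v0d2 had 3.59 ± 0.10.

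Proliferation genes were near background, while immediate-early genes were all called. The cell cycle list had 1 of 13 members above background by limma, Ccna2 (6.13 ± 0.49, SD, n = 3), and 0 adjusted over the list alone, with 1 at an unadjusted p below 0.05 and 2 above the threshold on all 3 arrays. Bub1 had 3.64 ± 0.15. Immediate-early genes, which respond within minutes to stimulation and to cell isolation, were above background in 18 of 18 cases, 18 adjusted over the list alone and 13 above the other-tissue background. Fosb stood at 10.13 ± 0.33, Ccn1 at 10.08 ± 0.52 and Dusp1 at 9.92 ± 0.07, and Ier3 at 6.22 ± 0.56. The calls of Ccna2 and Ier3 were lost without array 1 and without array 2. All 11 circadian clock genes were called, 11 adjusted over the list alone, and 3 passed the other-tissue background, namely Nr1d1 (9.09 ± 0.24), Nr1d2 (8.64 ± 0.24) and Clock (8.49 ± 0.17). Tef had 6.35 ± 0.09. Among 17 ubiquitous genes 17 were called, 17 adjusted over the list alone, and 15 lay above the other-tissue background, with Hspa8 at 12.32 ± 0.04, Actb at 11.88 ± 0.06, Hsp90ab1 at 11.66 ± 0.06 and Cct3 at 7.12 ± 0.39.

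The 10 genes with the highest mean outside the lists included B2m (12.77 ± 0.06, SD, n = 3), a component of MHC class I, the chaperone gene Hsp90b1 (12.15 ± 0.04), the interferon-inducible gene Ifitm3 (12.04 ± 0.07) and the tetraspanin gene Cd63 (11.95 ± 0.04). Esm1, which encodes a secreted proteoglycan, stood at 12.20 ± 0.09, and Sfrp4, which encodes a secreted Wnt antagonist, at 12.04 ± 0.19. The mitochondrial genes COX1 (12.55 ± 0.07), ND5 (12.07 ± 0.10) and COX3 (11.88 ± 0.10) and the transcript AY036118 (12.73 ± 0.04) completed the set. Probe affinity contributes to these values, and they do not rank the transcripts.

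Among the 28 lists, the endothelial list had the widest range over the 3 arrays. For 16 of the 17 endothelial genes array 2 was the lowest of the 3, and the list's median deviation was 0.29 on array 1, -0.89 on array 2 and 0.58 on array 3. The range of 1.48 on the log2 scale exceeded all 10000 level-matched random lists, of which 95% lay below 0.33. Over arrays 1 and 3 alone the range was 0.39, and a range over 2 arrays tends to be smaller than one over 3. The 10 called genes with the largest range were Gpm6a, Ubd, Mrc1, Sema3a, Cd36, 4930405O22Rik, Gimap4, Fabp4, Stab2 and Pcdhb9. All of them except Pcdhb9 were lowest on array 2 and lost their call without array 1. The lost calls do not show that array 1 carried these genes. In that fit limma's prior had 3.32 degrees of freedom, compared with 11.8 without array 3. Gpm6a had 10.15, 5.14 and 10.54 on arrays 1, 2 and 3, the scavenger receptor gene of sinusoidal endothelium Stab2 had 8.19, 5.88 and 9.55, and Cd36 had 9.84, 5.80 and 9.68. Pcdhb9 was higher on array 2, with 6.16, 9.70 and 6.72.

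Of the 28 lists 7 had a range above the 95th percentile of random lists, compared with 1.4 expected for lists of randomly drawn genes. Genes of a fixed list can vary together, which random lists leave out, so 1.4 is no chance level for the fixed lists. Besides the endothelial list, the pan-leukocyte list (0.62) and the neutrophil list (0.62) were highest on array 3, and so was the erythroid list (0.45). Without array 3 the pan-leukocyte range was 0.05 and the neutrophil range 0.20, and the erythroid range was 0.15 without array 1 and 0.12 without array 3. The immediate-early list (0.46) and the osteoblast list (0.43) were highest on array 1, with ranges of 0.19 and 0.09 when array 1 was left out. The B cell list (0.39) was highest on array 2 with 0.04 for the mean over probesets, 0.20 without array 1 and 0.08 without array 2. Above background were 0 of 11 B cell, 3 of 12 erythroid and 3 of 14 pan-leukocyte genes. The ranges of these lists therefore rest mostly on genes not above background. With only called genes used, 6 of the 22 lists that could be examined exceeded the 95th percentile. A range over 2 arrays tends to be smaller than one over 3 for any list. The smaller ranges with an array left out therefore do not by themselves trace a pattern to 1 array. The niche factor list had a range of 0.15 and the perivascular stromal list of 0.17, within those of random lists, and the ubiquitous list had 0.05. With 3 arrays of 1 group, no test can set 1 array apart from the others.

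**Figure D3:**
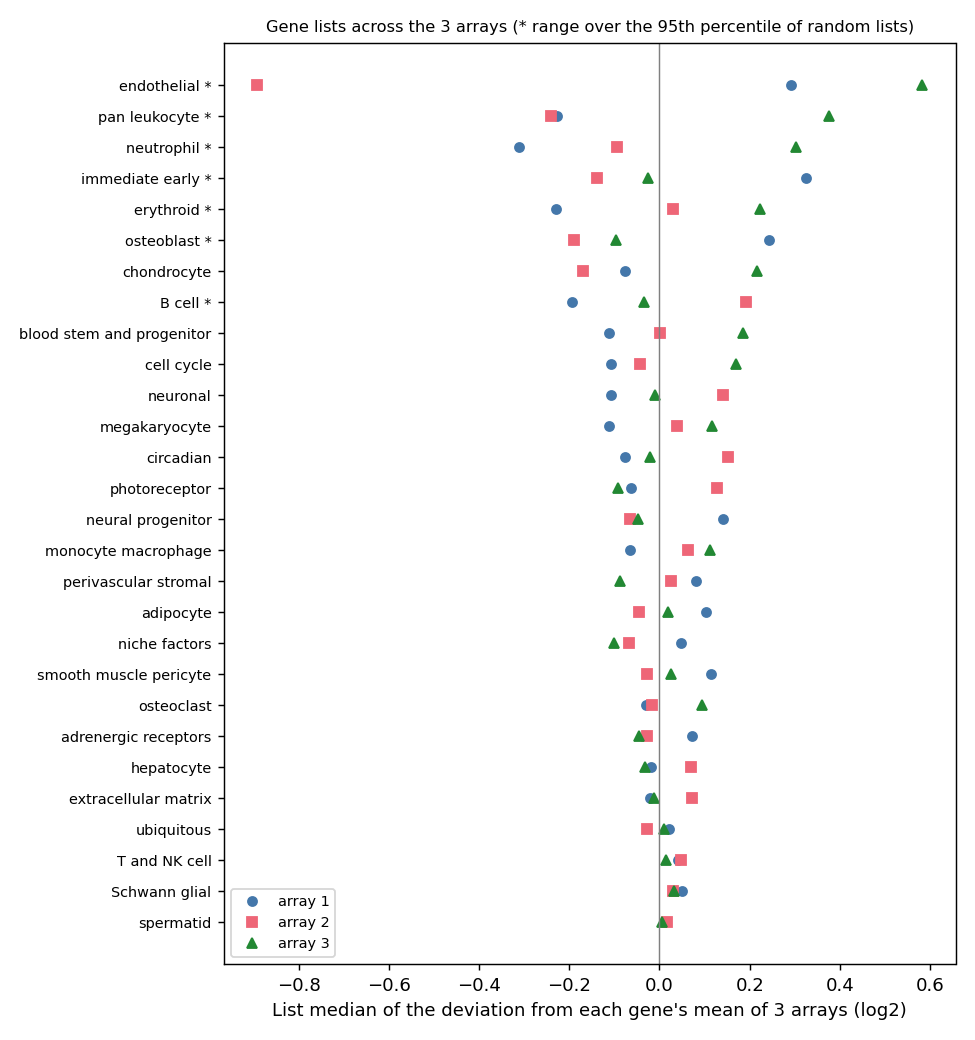
Median deviation of each gene list on the 3 arrays from the genes' means over the arrays (log2), with all-gene medians removed. An asterisk marks lists whose range exceeds the 95th percentile of level-matched random lists, and the endothelial list has the widest spread, with array 2 at -0.89.

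**Figure D4:**
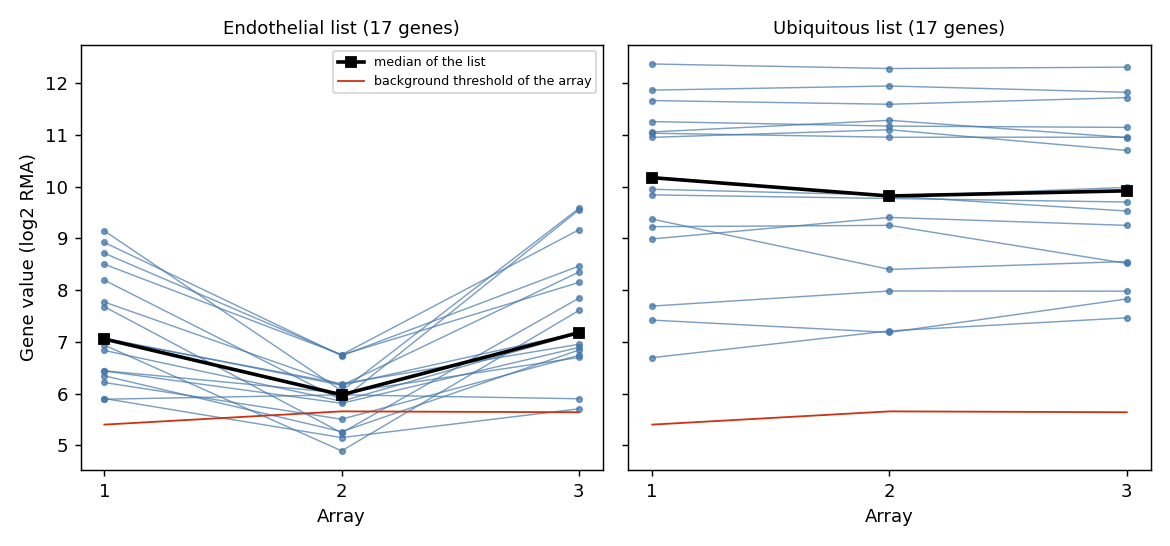
Log2 values on each array of the 17 endothelial genes (left) and the 17 ubiquitous genes (right), one thin line per gene. The black line is the list median and the red line the array's chemosensory background threshold. Endothelial genes drop on array 2 to a median of 5.98, near the threshold of 5.66.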

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

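The endothelial, macrophage and leukocyte tests in this part were chosen after the patterns had been seen in the first lists, on second gene lists that share no gene with those and whose values had not been seen.

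Probesets with no gene name, which entered no gene's value, carried signal. Of 931387 such probesets 32269 (3.46%) exceeded the 99th percentile of the chemosensory genes' probesets on all 3 arrays, compared with 0.753% of the chemosensory probesets themselves and 9.59% of probesets with 1 gene name.

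Endothelial genes differed between the 3 arrays, with array 2 lowest for 16 of 17. Spread at their expression level is argued against, because a second list of 21 measured endothelial genes had a range of 1.08, above 100% of 10000 level-matched lists. A different share of macrophages, considered because of Mrc1 and Cd36, is argued against as the whole cause: a second list of 16 macrophage genes deviated by 0.154 on array 2, its highest array, and its range lay within level-matched lists (92.0%), both as set in advance against macrophages. Genes near background could not fall, so the 8 of 29 macrophage genes of both lists above background were examined in a further test added after these values were seen. Their median deviation on array 2 was -0.01 (95% bootstrap interval over genes -0.49 to 0.29), and 2 of the 8, Mrc1 and Sirpa, were lowest there. The second endothelial list had -0.66 over all 21 measured genes, of which 14 were above background. The interval resamples genes and not samples, so it gives no spread between samples. A different share of endothelial cells among the sorted cells is a candidate explanation that the second list bears out, since 92.9% of its called genes (13 of 14), and 15 of all 21, were lowest on array 2. The exceptions were Icam2, which was called, and Nos3, Sox7, Oit3, Myct1 and Fcgr2b, which were not. Whether that came from the sort, the animal or endothelial expression itself stays open and was not tested. The labels do not say whether the samples came from separate sorts. Lower values on array 2 were not limited to endothelial lists, as Abcc9, Kcnj8, Postn and Fn1 were also lowest there. In their lists, 4 of 11 smooth muscle and pericyte genes and 5 of 18 extracellular matrix genes were lowest on array 2. No cause was tested for these genes.

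Leukocyte genes differed between the 3 arrays by a smaller amount. The range of a second leukocyte list exceeded 99.91% of level-matched lists, which argues against spread at that expression level. A different share of blood cells is a candidate explanation, as the second list deviated by 0.230 on array 3, but it also deviated by -0.23 on array 2, where 6 of its 8 genes above background were lowest, as endothelial genes were. In the second list 12 of the 19 measured genes were highest on array 3. Cybb, which was above both backgrounds, was lowest there, with 8.27, 9.43 and 7.79 on arrays 1, 2 and 3. Lcp2 (8.98, 8.48 and 7.96 on arrays 1, 2 and 3) and Rac2, called in the first list, were highest on array 1. The explanation may therefore cover only part of the pattern, and 11 of the 19 measured genes of the second list were not above background. The sort on GFP should remove most blood cells, and its purity was not measured in these data.

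Nes lay at the background threshold although its promoter drives the reporter. Whether the median over 23 probesets hides a signal cannot be settled. The 75th percentile over probesets put it 0.28 above the threshold with a standard error of 0.13, and it was not called (adjusted p = 0.0893, limma). The bound set in advance, a missing call, counted against a hidden signal, but a value above the threshold does not exclude one, and this reading was adopted after the value was seen. Of its probesets, 2 exceeded the 95th percentile of the chemosensory probesets on all 3 arrays, and 1 of them stood at 9.86 ± 0.17 (SD, n = 3). That probeset also exceeded their 99th percentile, which was 8.62, 8.97 and 8.79 on arrays 1, 2 and 3. Low transcript level and probe sensitivity stay open, and no biological explanation was tested.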

How the results depend on the processing

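The other-tissue background was chosen after seeing the data, as was the choice of the lists whose alternatives are given singly here. No named gene above background reversed its direction, taken as the sign of the margin over the background median. That sign could hardly change for a called gene, so the lack of reversals is no evidence of robustness. A call needs a mean above the thresholds, which were 5.40, 5.66 and 5.64 on arrays 1, 2 and 3. The background medians there were 3.40, 3.46 and 3.33. The highest background median under an alternative was 4.94, on array 2 with the other-tissue background. For 15 named genes not above background, such as Bub1 and Snap25, that sign changed under an alternative, and no direction is claimed for them. The sign was first taken from the margin over the threshold, which gave reversals almost only under the stricter backgrounds, and was redefined after those were seen. Under the other-tissue background 45 of 131 named genes changed their call, as did 44 with the 99th percentile, 44 with unnamed probesets as background and 36 with dim probesets left out, such as Nt5e and Rac2. Of 105 named genes above background, 60 were above under every alternative run. The signal over background therefore limits which genes can be called.

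With the 99th percentile, the unnamed background, dim probesets left out and the other-tissue background, the genes above background were 3798, 3652, 4343 and 3565 in place of 9548, and the list members 91, 91, 102 and 87 in place of 176 of 331. The 99th percentile is higher by construction, and the dim filter removes the background genes' own dim probesets. The unnamed and other-tissue backgrounds use the same percentile over other sets, and their thresholds came out above the chemosensory one, which is the lowest of these. In the same order the adipocyte list gave 4, 4, 4 and 4 in place of 7, the endothelial list 0, 0, 3 and 0 in place of 12, the pan-leukocyte list 1, 1, 1 and 1 in place of 3, and the cell cycle list 0, 0, 0 and 0 in place of 1. With at least 1 probeset the endothelial list gave 7, the pan-leukocyte list 1 and the cell cycle list 0. The cell cycle list gave 2 with the mean over probesets, 0 with their 75th percentile and 2 by the rule of each array above the threshold. With at least 8 probesets the immediate-early list gave 10 in place of 18, with fewer of its genes tested. Other causes were not tested.

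Leaving out each array in turn gave 8559 to 9158 genes, 152 to 176 list members, 7 to 15 endothelial, 2 to 4 pan-leukocyte and 0 to 1 cell cycle genes, and 4 to 7 lists over the 95th percentile of random lists. Without array 2 limma estimated an infinite prior degree of freedom (6.05 with all arrays, 3.32 without array 1 and 11.8 without array 3), so that fit gave all genes a variance in common and its calls ignore a gene's own spread. Calls lost only without array 1 can reflect the low prior of that fit, so they do not single out that array. Pearson's r of arrays 1 and 2, 1 and 3, and 2 and 3 was 0.933, 0.947 and 0.939 over genes and 0.841, 0.880 and 0.871 over probesets above the median of all 3 arrays, where a narrower range of values lowers r. Of 247 counts of the other 19 fixed lists under alternatives 155 stayed within 1.5 times, 81 were lower and 11 higher. Of 190 list ranges between arrays 172 stayed on their side of the 95th percentile, and of 1672 values of named genes 1414 kept their call, 251 lost it and 7 gained it. No paired analysis was possible because the samples form 1 group.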

Other observations

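The families in this part were chosen after the data were examined, and their counts use the same background tests as the lists.

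The share of members above background differed between families of secreted proteins, and no enrichment was tested. Of 27 measured genes of complement components and soluble regulators 14 lay above the chemosensory background and 7 above the other-tissue background. Among all genes these shares were 50.6% and 18.9%. The 7 included Serping1, C3, C1s1, C4b and Cfb. Serping1, which encodes the C1 inhibitor, stood at 11.48, the central component C3 at 11.21, C1s1 at 9.75, C4b at 9.56 and Cfb at 9.24. Of 7 insulin-like growth factor binding proteins 4 passed both, namely Igfbp5 (11.60), Igfbp4 (10.58), Igfbp7 (10.36) and Igfbp3 (8.30). All 3 called members of the 4 secreted frizzled-related genes passed both as well, with Sfrp1 at 9.53 and Sfrp2 at 7.48 beside Sfrp4. Of 19 Wnt genes 7 passed the chemosensory background, compared with 5 of 22 Fgf, 5 of 29 interleukin, 5 of 16 Ccl and 2 of 9 Tnfsf family genes, and with 50.6% of all genes. Above the other-tissue background there were 0 Wnt genes by limma, 1 Fgf gene, 2 interleukin, 1 Ccl and 2 Tnfsf family genes.

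Most members of the Fgf, interleukin and Tnfsf families were not called. Those above the other-tissue background were Fgf7 (11.05), Il34 (9.28), which encodes a ligand of the Csf1 receptor, Il7, Tnfsf12 (8.44) and the osteoclast factor gene Tnfsf11 (8.04). Of 13 measured Cxcl chemokines 8 passed the chemosensory background and 5 the other-tissue background. These were Cxcl12, Cxcl9 (9.69), Cxcl1 (8.96), Cxcl14 (8.55) and Cxcl10 (8.11), of which Cxcl9 and Cxcl10 are interferon-inducible. Of 9 Hoxa genes 7 lay above the chemosensory background, compared with 4 of 10 Hoxb, 2 of 8 Hoxc and 2 of 8 Hoxd genes, and Hoxa7 (7.74), Hoxa4 (7.60) and Hoxc6 (7.39) passed the stricter one. The differences between the clusters were not tested.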
